A study of Danio rerio with 4 samples.

How the data were processed

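Blood cells of zebrafish larvae at 5 days were measured by droplet single-cell RNA sequencing (10x 3' kit 3.1, per the labels). Per the labels, cells positive for a cd41 GFP reporter, a gata2b RFP reporter or both were sorted as live singlets from the anterior and posterior parts of about 100 larvae, with about 20000 cells loaded and 40000 reads per cell aimed at. The 4 libraries are anterior 1 and 2 and posterior 1 and 2. The labels do not say whether replicates of the same number came from the same larvae, so the main tests use region alone.

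The deposited matrices hold UMI counts for every barcode, unfiltered, per the file headers and the values themselves. The file headers name Cell Ranger 7.1.0, the design text in the labels names 6.1.2, and the processing notes name the tool with no version, so the version is unsettled. Reads were aligned by the authors to the Lawson lab annotation 4.3.2, per the labels. Whether intronic reads were counted is not given in the sources used here. The matrices list 36353 features, among them both transgenes; symbols listed more than once were kept apart by their gene identifier. No genome was used. The libraries hold 161821224, 146582104, 212914197 and 195908916 UMIs (anterior 1 and 2, posterior 1 and 2).

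Barcodes with at least 1000 UMIs, at least 300 genes and at most 20% of UMIs from 12 mitochondrial genes were kept: 7898, 7929, 9417 and 8052. Scrublet (scikit-image 0.26.0, scikit-learn 1.9.0) with an expected rate of 0.8% per 1000 cells marked 0, 1, 1 and 0 doublets by its automatic threshold in anterior 1, anterior 2, posterior 1 and posterior 2, so the highest-scoring cells up to the expected rate, 6.32, 6.34, 7.53 and 6.44%, were removed instead. All 4 libraries were clustered together with scanpy 1.11.5 (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, umap-learn 0.5.12, igraph 0.11.9, leidenalg 0.10.2, Python 3.11.15) on 3000 variable genes, 40 principal components and 15 neighbours at Leiden resolution 1 with seed 1, without integration. Of 37 clusters, 24 were haematopoietic, with 25787 of 31066 cells. Clusters were named from 18 fixed marker lists, and names carry "-like" because they rest on markers alone. The naming thresholds (score 0.8, margin 0.4, 3 markers at a log2 fold of 1, 10% detection, at least 1 marker of the list among the 10 leading genes, and for unnamed blood clusters 2 markers and coro1a at 400 or myb at 200 CPM) were set or revised after the clusters were seen. A cluster with median UMIs over 3-fold below the mean of its cells' library medians also stays unnamed if it shares more leading genes with another class than with its own, and counts as blood only if named. These rules leave 7 haematopoietic clusters unnamed (3, 4, 8, 10, 18, 19 and 22). Among the clusters they keep out are cluster 5 (8.07 and 4.48% of anterior and 0.138 and 0.186% of posterior cells), cluster 16 (10.6 and 8.97% against 0.942 and 1.06%) and cluster 36 (0.122 and 1.31% against 0 and 0%), which scored highest for neutrophil markers (2.51) and was kept out by its low UMIs.

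Counts were summed per class and library and tested with edgeR 4.0.16 quasi-likelihood (filterByExpr, TMM, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05, in classes with at least 20 cells in every library. Numbers of cells were tested the same way with the total of haematopoietic cells as offset. HSPC-like cells were clustered again at resolution 0.6 on 2000 genes and 20 components. The 24 gene lists, written before the data were examined, were S phase, G2/M, immediate early, heat shock, interferon, inflammatory, MHC class I, MHC class II, Hox 1 to 5, Hox 6 to 8, Hox 9 to 13, trafficking, glycolysis, haem synthesis, embryonic globins, adult globins, lysosome, myeloid, lymphoid, erythroid and thrombocyte, stem, Notch, ribosomal and mitochondrial. They were tested with camera at a preset correlation of 0.01. A few members are absent from the annotation: for example mhc2a for MHC class II and ikzf3 for the lymphoid list. Tests, filters, lists and the rule for names were chosen before the data were examined. The later choices are the naming thresholds above, leaving out of comparison by number any cluster with at least 3 of its 10 defining genes called, leaving erythroid-like cells out of the denominator, the free RNA profile of barcodes with over 50 and under 500 UMIs, and gene tests in unnamed clusters.

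Genes were named by a rule: adjusted p under 0.05, both libraries of one region above both of the other, and a mean of at least 20 CPM. The 12 largest changes per direction were taken in sums of all blood cells and in HSPC-like cells and the 5 largest elsewhere. gata2b and itga2b were added where tested, with up to 4 passing members of each list, or else the 2 highest. Unnamed loci were counted and not named, and only some of the list members that the rule picks are printed. Genes that define a cluster are not reported as results. A gene with 0 to 3 counts in a region is given by its counts and a Clopper-Pearson interval at 95%, with a floor of 3 counts for list medians.

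Free RNA was profiled in each library from barcodes with at most 50 UMIs, which hold 2.69, 2.13, 2.39 and 2.36% of UMIs (anterior 1 and 2, posterior 1 and 2). In each class and library the profile was scaled up until some gene with at least 500 counts in it would have supplied that gene's class count plus 3. The bound is the largest share of a gene's class counts that this scaled profile supplies in any library, and 10% was the limit for a low bound. A gene that limits the scaling reaches its full count in that library by construction. The library that sets a bound can lie in the region where the gene is lower. Such a bound does not show that free RNA could supply the excess in the other region. Alternatives were 500 or 2000 UMIs, 10% mitochondrial share, doublets kept, Leiden resolution 2, clustering on values centred within replicate number, replicate number as a block, DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, free RNA genes left out, other denominators, an estimated correlation, fry, other thinning, and each library left out in turn.

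The gene test was tested on simulated data with 200 changed genes per class. In HSPC-like cells it found 64 of 98 genes changed 2-fold (65.3%) and 96 of 99 changed 4-fold (97%), with 2 false among 162 calls. The values were 60.8 and 84.7% with 9 false of 151 calls in erythroid-like cells, 45.7 and 91.1% with 5 of 129 in thrombocyte-like cells, and 73.5 and 99% with 13 of 183 in sums of all blood cells. The test of shares called 2 of 6 unchanged classes in its first simulated draw. Over 200 draws it called 3% of unchanged classes at a dispersion of 0.01 and 2.25% at 0.05. An unchanged class was called in 28 and 23 of the 200 draws. The simulated classes were drawn independently, whereas real shares of a common total depend on each other. These error rates therefore do not cover shifts that a large class forces on the others. Libraries were checked for duplication: the chi-square per degree of freedom was 53.0 between the anterior pair and 85.1 between the posterior pair, far from that of a copy. Figures were drawn with matplotlib 3.10.9.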

Results

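Single-cell RNA was counted in reporter-positive cells sorted from zebrafish larvae at 5 days, whose anterior and posterior parts were processed apart. Each region has 2 libraries. The filters kept 7399 and 7426 cells in anterior replicates 1 and 2 and 8708 and 7533 in posterior replicates 1 and 2. Median depth was 14243 and 12426.5 UMIs per cell in the anterior libraries and 20438.5 and 21677 in the posterior ones, with 2778, 2395, 2955 and 2976 genes. Cells with blood markers numbered 5631, 5915, 7811 and 6430, which is 76.1, 79.7, 89.7 and 85.4% of the cells kept. Nothing in the labels says that the replicates came from separate animals. The p-values of gene and share tests therefore rest on the spread between these 4 libraries. That spread is pooled over genes, classes or clusters, so the same numbers of cells can give different p-values in different tests. The p-values of gene lists at the preset correlation compare the members of a list with other genes. An exact permutation of 2 against 2 libraries cannot go below a two-sided p of 0.333. Fold changes are anterior over posterior throughout, and an error given beside a log2 fold change is its standard error.

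Which blood cells lie in which region was asked first, and the regions held different ones. Erythroid-like cells, the red cell lineage, made up 5.38 ± 1.16% (mean ± SD) of blood cells in the anterior libraries and 71.8 ± 0.534% in the posterior ones (log2 fold change -3.74 ± 0.178, adjusted p = 1.29e-13). T-lymphoid-like cells numbered 765 and 765 in the anterior libraries and 1 and 0 in the posterior ones, a ratio of 1887 with a counting interval of 338.2 to 74590. The size of this difference depends on the clustering: the fitted fold was 1481, against 42.63 at resolution 2 and 99.02 with centred values, and 6356 without posterior replicate 1 and 899.6 without posterior replicate 2. Macrophage-like cells were at 18.4 ± 0.616% against 2.24 ± 0.138% (3.04 ± 0.182, adjusted p = 4.74e-12), a class that includes cluster 6, whose numbers are not compared on their own, so cluster 17 alone is given below. Neutrophil-like cells were at 8.98 ± 1.33% against 1.83 ± 0.231% (2.30 ± 0.185, adjusted p = 4.31e-10). NK-like or innate lymphoid-like cells were 160 and 147 against 4 and 6 (5.20 ± 0.331, adjusted p = 1.07e-11), and dendritic-like cells 79 and 76 against 4 and 3 (4.72 ± 0.392, adjusted p = 6.08e-10). HSPC-like cells, the stem and progenitor class, were 4.72 and 3.67% of anterior and 7.05 and 6.42% of posterior blood cells (-0.69 ± 0.174, adjusted p = 9.55e-04). Thrombocyte-like cells were 0.921 ± 0.179% against 2.37 ± 0.619% (-1.37 ± 0.219, adjusted p = 7.27e-06). The test is edgeR quasi-likelihood on numbers of cells with Benjamini-Hochberg adjustment over the classes. Shares rest on barcodes with at least 1000 UMIs and 300 genes after 6.32, 6.34, 7.53 and 6.44% of them were removed as doublets (anterior 1 and 2, posterior 1 and 2). The median UMIs per cell were 29440.5 and 25758 in anterior against 18654 and 20262 in posterior HSPC-like cells, and 36673 and 34536 against 23604.5 and 25349 in erythroid-like cells. Counting intervals here and below are Clopper-Pearson intervals and cover counting error only.

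**Figure D1:**
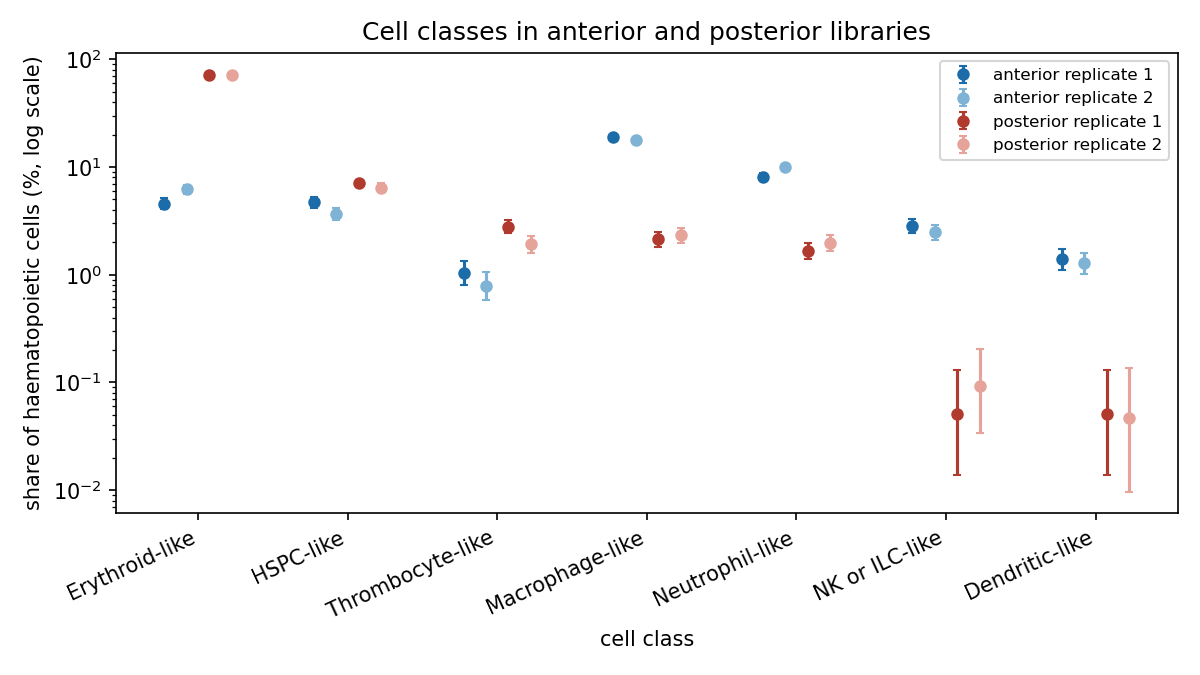
Share of blood cells per library on a log axis, for erythroid-, HSPC-, thrombocyte-, macrophage-, neutrophil-, NK or ILC- and dendritic-like cells. T-lymphoid-like cells, the lymphoid-like cluster and the unnamed clusters are not drawn. Bars are 95% counting intervals.

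Since erythroid-like cells fill most of the posterior libraries, the size of the other shifts depends on the denominator. Without erythroid-like cells the HSPC-like log2 fold change was -2.43, the thrombocyte-like one -3.12, the macrophage-like one 1.3 and the neutrophil-like one 0.56. With that denominator it was 8.95 for T-lymphoid-like, 3.48 for NK-like or innate lymphoid-like and 3.00 for dendritic-like cells. A lymphoid-like cluster, which scored highest for the T markers with another lymphoid list within the naming margin of 0.4, held 794 and 773 anterior and 41 and 46 posterior cells. Its defining genes themselves differ between regions, so no test is reported for it.

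Below the level of classes, every haematopoietic cluster that was tested passed the threshold, 24 in all. Of these, clusters 4, 6, 11 and 18 are not compared by number because at least 3 of their 10 defining genes differ between regions. This check needs gene tests, so it was not made in clusters 0, 8, 19, 20, 21 and 22, which had under 20 cells in some library. Cluster 17, the macrophage-like cluster without that problem, was 9.73 and 9.26% against 0.871 and 0.933% (3.4 ± 0.219, adjusted p = 2.29e-06). Cluster 10, marked by blf, znfl2a, tal1 and the GFP transgene and named by no marker list, was 5.79 and 5.95% against 10.3 and 12.5% (-0.95, adjusted p = 0.0019). Its best score was for the HSPC markers (0.880), with the thrombocyte markers (0.807) within the naming margin, so the HSPC-like class leaves it out. It held 2284 cells with myb at 446 CPM, against 1447 cells and 136 CPM in the HSPC-like cluster. Cluster 3 was 8.93 and 7.90% against 0.819 and 0.575% (3.58, adjusted p = 2.95e-06), and cluster 22 was 2.84 and 3.42% against 0.154 and 0.187% (4.20, adjusted p = 2.41e-06). The il13-rich cluster 8 was 2.13 and 2.40% against 0.256 and 0.233% (3.2, adjusted p = 4.12e-06). The HSPC-like cluster alone had a log2 fold change of -0.68 (adjusted p = 0.0144), which became -0.61 (adjusted p = 0.0546) without posterior replicate 1 and -0.51 (adjusted p = 0.182) without anterior replicate 2.

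Sums of all blood cells carry this composition. In the anterior sums, genes of lymphocytes rose: rag1, which cuts DNA at antigen receptor loci, had 15256 counts against 1, a ratio of 22400 with a counting interval of 4020 to 884800. The lymphoid regulators satb1b (6.17 ± 0.18), rorc (5.80 ± 0.14), gata3 (4.81 ± 0.15), runx3 (4.40 ± 0.12) and ikzf2 (4.37 ± 0.14) rose with the cytokine receptor il7r (4.69 ± 0.18), the adaptor sla2 (4.63 ± 0.11) and the costimulatory receptor tnfrsf9b (5.04 ± 0.21). The chemokines ccl36.1 (4.83 ± 0.34) and ccl20a.3 (4.28 ± 0.13) rose as well, as did spink2.2 (4.58 ± 0.49), whose near-identical copies make its counts uncertain. Posterior sums held the red cell genes. The embryonic globin hbbe1.1 fell from 30500 and 31170 CPM in posterior to 2071 and 2942 CPM in anterior sums (-3.62 ± 0.25), and hbbe2 (-3.52 ± 0.27), hbae3 (-3.43 ± 0.24), hbae5 (-3.41 ± 0.17) and hbbe1.2 (-3.36 ± 0.36) fell too, though counting may split reads among globin paralogs. The membrane skeleton genes epb41b (-3.40 ± 0.17) and tmod4 (-3.33 ± 0.17), the carbonic anhydrase cahz (-3.34 ± 0.23), the water channel aqp1a.1 (-3.32 ± 0.13), lamc3 (-3.43 ± 0.17), cntn3b (-3.33 ± 0.20) and eevs (-3.52 ± 0.43), an enzyme of gadusol synthesis, fell with them. The reporter genes moved apart: gata2b rose (0.57 ± 0.0977, adjusted p = 0.00137) and itga2b, which encodes CD41, fell (-1.72 ± 0.34, adjusted p = 0.00302). Of 24015 genes tested with edgeR quasi-likelihood, 15467 passed an adjusted p of 0.05, 8122 higher in anterior and 7345 higher in posterior sums. The larger side turns with the scaling: 6380 against 7354 by DESeq2, and 7766 against 7871 by edgeR with the size factors of DESeq2. The median log2 fold change of all genes was 0.092 by this scaling and 0.111 by that of DESeq2. Free RNA could supply over 10% of the counts in at least 1 library for 2606 of the genes called.

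The gene lists were tested in the same sums, where composition and change within cells are not separated. The test is camera with a preset correlation of 0.01, which called 18 of 24 lists. With an estimated correlation 0 were called, the lowest adjusted p being 0.250. That setting estimates the correlation from 4 libraries and has little power, here and below, so a list it does not call is left undecided. Lymphoid factors had a median log2 fold change of 4.28 (11 of 14 called higher in anterior and 2 in posterior sums, adjusted p = 5.98e-04), with lck at 5.80 and tcf7 at 5.47. Myeloid factors had 2.44 (14 of 14, adjusted p = 8.43e-06), with gfi1aa at 3.82, spi1b at 3.14 and the macrophage receptor csf1ra at 2.78. The macrophage marker grn1, a member of the lysosomal list and not of this one, was at 4.06. Erythroid and thrombocyte factors had -2.74 (1 of 11 higher and 9 lower, adjusted p = 4.54e-04), with gata1a at -3.11, gfi1b at -3.15 and tal1 at -2.74. Haem synthesis had -2.60 (2 of 13 higher and 11 lower, adjusted p = 2.34e-04), with fech at -2.60 and the iron carrier slc25a37 at -2.57. Embryonic globins had -3.41 (9 of 9 lower, adjusted p = 3.97e-05) and adult globins -3.2, or -2.97 with 1 member at its floor (4 of 4 lower, adjusted p = 0.0215), where hbba2 was at -2.69 and hbaa1 at -3.81. Cell cycle lists were lower in anterior sums: S phase -0.721 (19 of 20, adjusted p = 6.21e-06), with cdc45 at -1.20 and uhrf1 at -1.10, and G2/M -0.973 (20 of 20, adjusted p = 4.76e-07), with tpx2 at -1.15, bub1 at -1.13 and cdk1 at -1.12. Immediate early genes had 2.25 (19 of 20 higher, adjusted p = 6.21e-06), with dusp2 at 3.95, egr1 at 3.61 and socs3a at 2.96. Inflammatory genes had 1.84 (17 of 18, adjusted p = 3.97e-05), with nfkbiaa at 2.82, rel at 2.80 and il1b near 2.79, and interferon genes 1.24 (12 of 16 higher and 1 lower, adjusted p = 0.00445), where irf7 was at 2.43 and irf9 at -1.43.

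The further lists in the same sums follow, first those that passed at the preset correlation and then those that did not. Trafficking genes had 2.50 (17 of 21 higher and 3 lower, adjusted p = 5.95e-04), with the homing receptor ccr9b at 6.24 and the integrin itgb7 at 3.95. Notch genes had 1.31 (14 of 20 higher and 2 lower, adjusted p = 0.00335, or 15 and 2 adjusted over the list alone), with the ligand jag1a at 4.1, her9 at 3.70 and notch2 at 2.43. Glycolysis had 0.799 (18 of 25 higher and 2 lower, adjusted p = 0.00124, or 20 and 2 adjusted over the list alone), with pfkpa at 1.68 and ldha at 0.93. MHC class I had 0.812 (12 of 16 higher and 1 lower, adjusted p = 0.00294, or 14 and 1 adjusted over the list alone), with psmb9a at 2.75 and psmb8a at 2.15. Hox genes 9 to 13 had -1.44 (11 of 15 lower, adjusted p = 4.54e-04), with hoxc11a at -2.02 and hoxd12a at 1 count against 59, a ratio of 0.0249 with an interval of 6.2e-04 to 0.144, where free RNA could supply all of the counts. Ribosomal proteins had -0.608 (6 of 94 higher and 72 lower, adjusted p = 2.93e-08, or 6 and 75 adjusted over the list alone), although the name pattern also takes kinases such as rps6ka1 at 3.1 and rps6kb1a at -1.09. Genes of the mitochondrial genome had -0.358 (5 of 12 lower, adjusted p = 0.0305), with mt-nd5 at -0.56. MHC class II had 2.92 (6 of 8 higher and 2 lower, adjusted p = 0.0678), with cd74b at 3.17 and cd74a at 3.15. Hox genes 1 to 5 had 0.679 (4 of 9 higher, 3 adjusted over the list alone, adjusted p = 0.132), with hoxb3a near 1.22, which fell to 0.21 (adjusted p = 0.548) with doublets kept, and Hox 6 to 8 had 0.703 (1 of 5, 0 adjusted over the list alone, adjusted p = 0.359). Their called member hoxc8a (0.86, adjusted p = 0.0488) lost its call without any 1 library, at 0.119 without anterior replicate 1, 0.129 without anterior replicate 2, 0.0908 without posterior replicate 1 and 0.245 without posterior replicate 2. hoxc8a also lost it with DESeq2 (0.29), with its size factors in edgeR (0.0615), without a filter (0.0659) and with doublets kept (0.08). Heat shock had -0.0844 (1 of 14 higher and 2 lower, adjusted p = 0.359), with hsp90aa1.2 at -1.60, and lysosomal genes 0.158 (10 of 24 higher and 5 lower, adjusted p = 0.453), with cd63 near 1.83. Stem factors had a median of 0.242 but a mean of -0.0436 and a test direction towards posterior (6 of 17 higher and 4 lower, adjusted p = 0.982), with kita at -1.58, myb near -1.72 and cbfb at 1.0.

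HSPC-like cells were compared on their own. Anterior cells had more of the thymosin tmsb (1.81 ± 0.15, adjusted p = 4.48e-04), the creatine kinase ckbb (1.55 ± 0.19, adjusted p = 0.00301), the respiratory chain gene ndufa4 (1.48 ± 0.14, adjusted p = 6.11e-04) and the protease gene furinb (1.69 ± 0.28, adjusted p = 0.0178). The lower changes were in cox8b (0.90 ± 0.18, adjusted p = 0.0485), ggps1 (0.88 ± 0.14, adjusted p = 0.0185), the mitochondrial carrier slc25a25a (0.89 ± 0.14, adjusted p = 0.0169), the AP-1 genes junba (0.67 ± 0.13, adjusted p = 0.0387) and fosab (0.63 ± 0.12, adjusted p = 0.0414), and midn (0.57 ± 0.11, adjusted p = 0.0496). The NF-kB regulator bcl3 (1.51 ± 0.28, adjusted p = 0.0387), the BMP receptor bmpr1ba (1.46 ± 0.25, adjusted p = 0.0242) and the stress gene ddit3 (0.98 ± 0.17, adjusted p = 0.0242) rose too. Posterior cells had more of the haem-binding gene soul5 (-0.82 ± 0.11, adjusted p = 0.00483), tspo (-0.76 ± 0.11, adjusted p = 0.00802) and the prostaglandin D synthase ptgdsb.2 (-0.85 ± 0.15, adjusted p = 0.0242). The reporter gene gata2b was at 95 and 95.3 against 78.7 and 82.9 CPM (0.24 ± 0.0958, adjusted p = 0.462), and itga2b had 1 and 0 against 0 and 1 UMIs. Some of these genes define subclusters whose mix differs between libraries, so their changes also compare different mixes. tmsb, ckbb and ptgdsb.2 are among the 10 defining genes of subcluster 7, with 3 and 32 anterior and 58 and 70 posterior cells. At resolution 1 tmsb, ckbb and cox8b are among those of subcluster 11, with 2 and 18 against 7 and 7. The genes tmsb, furinb, slc25a25a, bcl3, bmpr1ba, ddit3, soul5 and tspo were chosen after their values were seen.

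The largest differences in these cells belong to genes with a high free RNA bound. A bound is an upper limit on what free RNA supplies. For genes higher in posterior cells, every bound given below except that of hbbe1.1 is too small to give the whole fold. Among the 10 defining genes of subcluster 5 are hbbe1.1, hbbe1.2, hbbe1.3, hbae3, hbbe2, hbae1.3, hbae1.1 and slc4a1a. That subcluster held 23 and 13 anterior and 41 and 29 posterior cells. hbbe1.1 was at 45.3 and 27.8 against 761 and 1053 CPM (-4.62 ± 0.23), with a bound of 102%. It limited the scaling in anterior replicate 2, where it was lower, so it reached its full count there by construction. Its bound therefore does not show that free RNA could supply the posterior excess. For hbae3 (-4.43 ± 0.30), hbbe2 (-4.37 ± 0.26), hbbe1.3 (-4.24 ± 0.29), hbbe1.2 (-4.23 ± 0.31) and hbae1.3 (-3.15 ± 0.25) that bound was 76.0, 91.0, 71.4, 77.4 and 54.0%. It was 45.6% for the anion exchanger slc4a1a (-3.02 ± 0.34), 45.9% for hemgn (-3.43 ± 0.22), 41.3% for hbae1.1 (-1.55 ± 0.20), 37.4% for blvrb (-1.71 ± 0.14), 25.4% for znfl2a (-1 ± 0.14), 20.2% for urod (-0.84 ± 0.11) and 19.0% for hmbsb (-1.32 ± 0.20). In the anterior direction lyz (2.46 ± 0.28), a neutrophil enzyme, had a bound of 101%, and ckbb had 7.48% by the first profile and 10.3% by the second. By the first profile lyz limited the scaling in posterior replicate 1, where it was lower, so its bound does not account for the anterior excess. It also limited a posterior library in erythroid-, thrombocyte-, macrophage- and lymphoid-like cells and clusters 3, 4 and 10. In thrombocyte-like cells it limited anterior replicate 2 as well. Of 13513 genes, 148 were called, 108 higher in anterior and 40 in posterior cells, and 122 of the 148 had a bound over 10%. That count takes the highest bound from either region, so it does not show how many calls free RNA could give. By both free RNA profiles 24 had a bound of 10% or less, 16 higher in anterior and 8 in posterior cells. When genes with a higher bound were left out before the test, 6 were called by the profile of barcodes with at most 50 UMIs and 3 by that of barcodes with over 50 and under 500. Of the 30 genes named here that passed, 21 kept their call without any 1 library. Without anterior replicate 2 cox8b, ggps1, junba, fosab, midn, bcl3 and bmpr1ba lost theirs (adjusted p 0.0534 to 0.238). So did junba, ptgdsb.2 and ddit3 without anterior replicate 1 (0.0501 to 0.099), cox8b, midn and ddit3 without posterior replicate 1 (0.0786 to 0.121) and junba, fosab and midn without posterior replicate 2 (0.0714 to 0.116). With free RNA genes left out before the test, 16 of the 30 were still tested and 4 kept their call, while cox8b, ggps1, junba, fosab, midn, ptgdsb.2, tspo, furinb, slc25a25a, bcl3, ddit3 and bmpr1ba lost it (0.0631 to 0.213). By the second profile 2 of 18 kept theirs, with soul5 also among the lost (0.0521 to 0.213). The lost genes themselves had a low bound, since they stayed in the test. Genes at unadjusted p under 0.05 by edgeR were 1302 of 13513 before and 1122 of 13069 after the first profile's genes were left out. Taking out genes with small p-values can raise the adjusted p of the rest, so these losses do not show that a gene depends on free RNA. DESeq2 did not call cox8b, junba, midn, slc4a1a, slc25a25a, bcl3, ddit3 and bmpr1ba (0.101 to 0.429). The clustering mattered as well: fosab, midn, bcl3 and bmpr1ba lost their call at resolution 2 (0.0593 to 0.592), and with centred values these, cox8b and ddit3 did (0.0507 to 0.51).

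**Figure D2:**
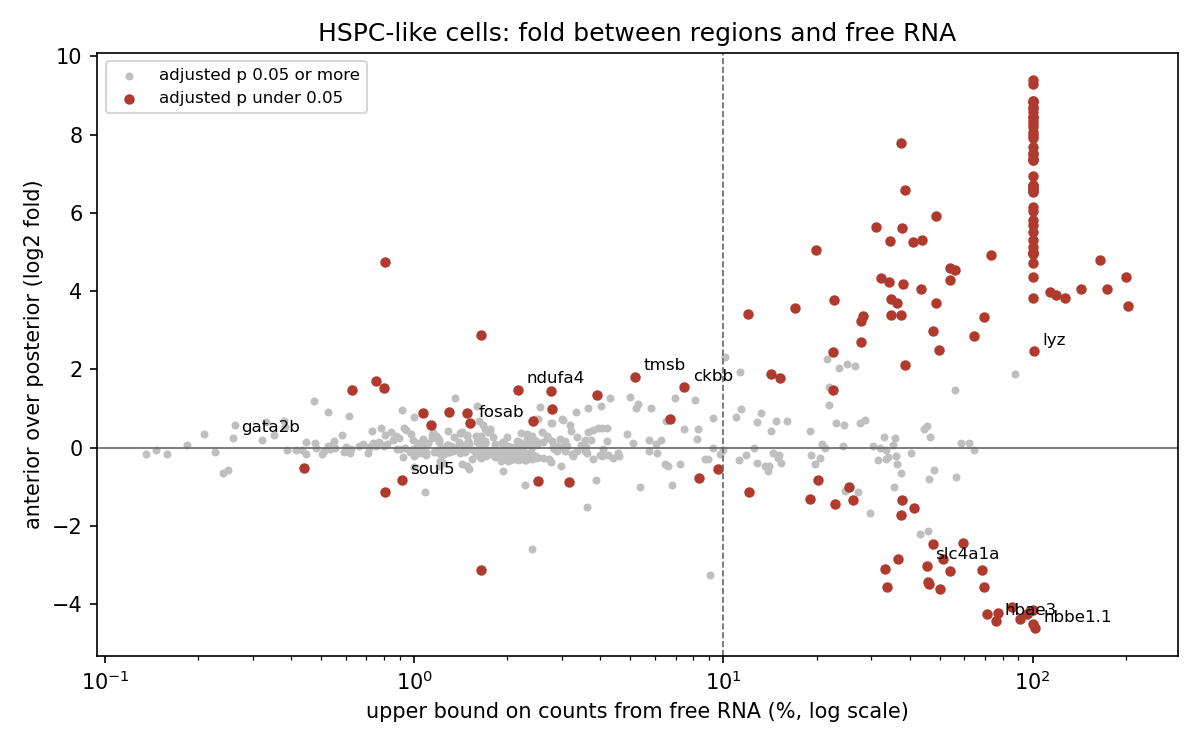
Fold change between regions in HSPC-like cells against the highest share of counts that free RNA could supply, for genes called and genes of the lists. The dashed line marks 10%.

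Programmes inside HSPC-like cells were tested with the same lists. The list tests, here and in the classes below, kept genes with a high free RNA bound. How far free RNA moved a list was not tested. Immediate early genes had a median of 0.389 (2 of 19 called, 6 adjusted over the list alone, adjusted p = 0.00129, and adjusted p = 0.428 with an estimated correlation). Embryonic globins had -4.24 (8 of 8 lower, adjusted p = 2.47e-16; 0.428 with an estimated correlation) and haem synthesis -0.345 (3 of 12 lower, 4 adjusted over the list alone, adjusted p = 2.91e-06; 0.428 with an estimated correlation). Ribosomal proteins had -0.204 with rps20 at -0.27 (0 of 91 called, adjusted p = 5.89e-08; 0.447 with an estimated correlation). Hox genes 9 to 13 had -0.895 (0 of 8 called, 2 adjusted over the list alone, adjusted p = 6.49e-05; 0.441 with an estimated correlation), with hoxc9a at -0.64. MHC class II had 0.344 (0 of 7, 2 adjusted over the list alone, adjusted p = 0.00387; 0.428 with an estimated correlation), with cd74b at 0.40 and ctss2.1 at 0.34, a gene with a near copy. Lymphoid factors had 0.498 (0 of 9, 3 adjusted over the list alone, adjusted p = 0.00425; 0.441 with an estimated correlation), with ikzf1 at 0.06. Erythroid and thrombocyte factors had -0.30 (1 of 8 lower, 2 higher and 3 lower adjusted over the list alone, adjusted p = 0.0173; 0.441 with an estimated correlation), interferon genes 0.230 with stat1a at 0.31 (0 of 10, adjusted p = 0.0287; 0.518 with an estimated correlation), and Notch genes 0.197 with rbpjb at 0.25 and notch1b at -0.06 (0 of 12, 1 adjusted over the list alone, adjusted p = 0.0344; 0.441 with an estimated correlation).

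The remaining lists did not pass in HSPC-like cells. S phase had -0.0493 (0 of 20 called, adjusted p = 0.477), with pcna at 0.05, and G2/M -0.0918 (0 of 20, adjusted p = 0.126), with mki67 at -0.11 and top2a at -0.20. Trafficking had 0.267 (0 of 16, 4 adjusted over the list alone, adjusted p = 0.0632), with the niche receptor cxcr4b at 0.23 and the integrin itga4 at -0.16. Hox genes 1 to 5 had 0.473 with hoxc3a at 0.40 (0 of 3, adjusted p = 0.067), and Hox 6 to 8 had 1 member tested and no list test. Stem factors had 0.0897 (0 of 14, adjusted p = 0.343), with lmo2 at -0.31. Inflammatory genes had 0.169 with rel at 0.47 (0 of 11, 2 adjusted over the list alone, adjusted p = 0.229), myeloid factors 0.203 (1 of 10, 3 adjusted over the list alone, adjusted p = 0.413), and lysosomal genes -0.0161 with cd63 at -0.10 (0 of 20, adjusted p = 0.413). MHC class I had a median of -0.00486 and a mean of 0.0836 with psme1 at -0.17 (0 of 14, adjusted p = 0.841). Genes of the mitochondrial genome had a median of 0.0312 and a test direction towards posterior with mt-co2 at -0.08 (0 of 12, adjusted p = 0.791). Glycolysis had -0.016 with gapdhs at -0.10 (0 of 21, adjusted p = 0.807) and heat shock 0.0593 with hspa8 at -0.13 (0 of 13, 1 adjusted over the list alone, adjusted p = 0.807). No adult globin was tested. At unadjusted p under 0.05 edgeR had 1302 genes in these cells, and DESeq2 called 108 genes.

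Cycling and diversity of HSPC-like cells were compared next. Cells with at least 2 UMIs of G2/M genes, after thinning to 1000 UMIs, were 25.2 and 27.2% of anterior and 25.8 and 23.2% of posterior HSPC-like cells (26.2 ± 1.41 against 24.5 ± 1.79%, exact permutation p = 0.667). Thinning left out 0 cells. The shares unthinned were 91.0 and 82.0% against 81.5 and 81.4%. Within the class 9 subclusters were found, and edgeR called 0 of them, with 0 at unadjusted p under 0.05. Standard errors of their log2 fold changes were 0.535 to 0.705, so shifts of moderate size could go uncalled. At resolution 1 subclusters 9 and 10 had unadjusted p of 0.0379 and 0.0328 by the same edgeR test (adjusted p = 0.266 for each). Subcluster 0 (nanos1, cdh4, zfpm1, meis1b) was 6.39 and 11.1% against 6.17 and 6.30% and subcluster 6 (s1pr4, ackr3a, runx3, klf2a) 9.77 and 11.1% against 5.81 and 7.02%. The histone-rich subcluster 1 was 30.1 and 24.0% against 24.1 and 28.6%, and the dividing subcluster 3 (nusap1, ccnb1, ube2c) 8.65 and 5.53% against 10.3 and 8.23%. Subclusters 5 and 7 are not compared because their defining genes differ between regions. Without anterior replicate 2, 1 subcluster passed, which was subcluster 7 (near -3.56, adjusted p = 0.00993).

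Both transgenes were counted. GFP was found in 83.8 and 74.2% of anterior and 78.0 and 68.0% of posterior HSPC-like cells, against 10.1, 4.90, 9.76 and 4.62% of erythroid-like cells (libraries in the order anterior 1, anterior 2, posterior 1, posterior 2). All cells were sorted on these reporters, so no class here is a background free of them. Median depth was 29440.5 and 25758 against 18654 and 20262 UMIs in HSPC-like cells, and 36673, 34536, 23604.5 and 25349 in erythroid-like cells. After thinning the HSPC-like GFP shares were 21.8, 14.7, 19.6 and 13.3%. RFP was found in 19.9 and 15.7% against 16.5 and 19.9% of HSPC-like cells (7.14, 8.29, 9.44 and 10.9% thinned), with 3.11, 1.09, 0.905 and 0.719% in erythroid-like cells. HSPC-like sums held 190 and 204 against 260 and 265 CPM of RFP, which is not tested as a result since it helps define the cluster.

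Erythroid-like cells differed in few genes with a low free RNA bound. Anterior cells had more fosb (3.21 ± 0.46, adjusted p = 0.0067), an AP-1 gene, and ndufa4 (1.01 ± 0.14, adjusted p = 0.00496), and b3gnt3.4, a glycosyltransferase gene, was at 0.53 ± 0.10 (adjusted p = 0.0297). The embryonic globin hbbe3 (-1.88 ± 0.18, adjusted p = 5.92e-04) and soul5 (-1.05 ± 0.13, adjusted p = 0.00277) were higher in posterior cells, and gata2b was at -0.11 ± 0.39 (adjusted p = 0.940). lyz (2.98 ± 0.26) had a free RNA bound of 100%. soul5 and ndufa4 were chosen after their values were seen. Of 18095 genes, 391 were called, 380 higher in anterior cells and 11 in posterior ones; 364 had a bound over 10%, and 25 had a low bound by both profiles (19 and 6). Of 6 named genes that passed, 3 kept their call without any 1 library: b3gnt3.4, fosb and ndufa4 lost it without anterior replicate 1 (adjusted p 0.052 to 0.122), and b3gnt3.4 without anterior replicate 2 (0.207). With free RNA genes left out by the profile of at most 50 UMIs, b3gnt3.4, fosb, soul5 and ndufa4 lost their call (0.0812 to 0.242). By the second profile 4 of 5 tested kept theirs and b3gnt3.4 did not (0.0956), and fosb lost its call at resolution 2 (0.148) and with centred values (0.181). b3gnt3.4 also lost its call without a filter on low counts (0.117), and with doublets kept lyz and b3gnt3.4 did (0.0545 to 0.0993). The class joins 7 clusters whose mix differs, so its changes also compare different mixes. Cluster 31 held 9 of 257 and 40 of 367 anterior and 811 of 5636 and 577 of 4591 posterior cells, and cluster 27 held 7 and 12 against 452 and 157. Cluster 27 had a median of 2261 UMIs and a median mitochondrial share of 6.11%, against 25738 UMIs and 1.04% in cluster 31. Lists called were immediate early (1.27, 6 of 19, 13 adjusted over the list alone, adjusted p = 6.93e-07), myeloid 2.11, lymphoid 2.18, MHC class II 1.89, trafficking 0.758, Hox 9 to 13 -2.07, ribosomal -0.257 and G2/M -0.135. With an estimated correlation the lowest adjusted p was 0.365. Genes with a bound over 10% were kept in these list tests, so free RNA and expression in these cells are not told apart.

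Thrombocyte-like cells of the anterior libraries had more fosab (1.1 ± 0.21, adjusted p = 2.16e-04), junba (1.14 ± 0.31, adjusted p = 0.0374), the amino acid carrier slc38a2 (1.24 ± 0.26, adjusted p = 0.00153) and tmsb (2.19 ± 0.43, adjusted p = 3.77e-04, with bounds of 9.98 and 11.6% by the 2 free RNA profiles). Posterior cells had more of the mitotic genes kif11 (-1.28 ± 0.31, adjusted p = 0.0105) and nusap1 (-1.01 ± 0.26, adjusted p = 0.0213) and of the actin-binding gene tagln2 (-0.92 ± 0.20, adjusted p = 0.00261). itga2b was at -0.42 ± 0.21 (adjusted p = 0.683). apoa2 (53 counts against 5, a ratio of 24.9, interval 10.03 to 79.8), apoa1b (3.88 ± 0.51), gch2 (2.49 ± 0.46) and lyz (2.28 ± 0.26) had bounds of 100, 22.3, 35.2 and 114%. The red cell genes hbae3 (-5.19 ± 0.26), hbbe1.3 (-4.66 ± 0.22), hbbe2 (-4.49 ± 0.26), hbbe1.1 (near -4.04) and cahz (2 counts against 137, a ratio of 0.0343, interval 0.00411 to 0.126) had bounds of 51.3 to 123%. slc38a2 and tagln2 were chosen after their values were seen. Of 6088 genes 72 were called, 49 higher in anterior and 23 in posterior cells, and 60 had a bound over 10% while 10 had a low one by both profiles (7 and 3). Of 16 named genes 9 kept their call without any 1 library. Lost were tmsb, junba, kif11 and nusap1 without anterior replicate 1 (adjusted p 0.0533 to 0.217), those and tagln2 without posterior replicate 1 (0.0594 to 0.409), junba, kif11 and nusap1 without anterior replicate 2 (0.0625 to 0.281), and fosab, junba, slc38a2, kif11, nusap1 and tagln2 without posterior replicate 2 (0.161 to 0.527). DESeq2 did not call gch2, tmsb, junba, slc38a2, kif11 and nusap1 (0.191 to 1), and with free RNA genes left out junba and nusap1 were lost by both profiles (0.0753 to 0.083 and 0.0672 to 0.0818). Lists called were G2/M -0.404 (adjusted p = 1.88e-04), S phase 0.342, immediate early 0.437 (adjusted p = 0.00693), inflammatory 0.505, glycolysis 0.228, haem synthesis -0.579, embryonic globins -4.04, myeloid 0.255, erythroid and thrombocyte factors -0.196 and Notch -0.48, and with an estimated correlation the lowest adjusted p was 0.329.

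Neutrophil-like cells of the anterior libraries had more ndufa4 (2.42 ± 0.25, adjusted p = 1.15e-04) and cox6b1 (1.24 ± 0.18, adjusted p = 0.00176) of the respiratory chain, the amino acid carriers slc1a5 (0.97 ± 0.18, adjusted p = 0.0117) and slc38a2 (0.80 ± 0.18, adjusted p = 0.0484), and the deiminase padi2 (1.42 ± 0.27, adjusted p = 0.0114). Posterior cells had more nusap1 (-1.09 ± 0.24, adjusted p = 0.0319) and ube2c (-0.99 ± 0.23, adjusted p = 0.0497), which act in mitosis, and the glucocorticoid target tsc22d3 (-0.97 ± 0.19, adjusted p = 0.019). gata2b was at -0.32 ± 0.65 (adjusted p = 0.956). The red cell genes hbbe1.1 (-5.94 ± 0.61), hbbe2 (-5.71 ± 0.56), hbae3 (-5.24 ± 0.54), hbae1.3 (-5.01 ± 0.58) and slc4a1a (-4.54 ± 0.34) had bounds of 87.6, 100, 101, 71.5 and 49.8%. padi2 and tsc22d3 were chosen after their values were seen. Of 11435 genes 151 were called, 78 higher in anterior and 73 in posterior cells, and 131 had a bound over 10% while 20 had a low one by both profiles (10 and 10). Of 13 named genes 7 kept their call without any 1 library. nusap1 and ube2c lost it without anterior replicate 1 (adjusted p = 0.121), slc38a2 and tsc22d3 without anterior replicate 2 (0.126 to 0.168), and slc1a5, slc38a2, nusap1, ube2c and padi2 without posterior replicate 2 (0.0684 to 0.469). All of slc1a5, slc38a2, nusap1, ube2c, padi2 and tsc22d3 lost their call under DESeq2 (0.0652 to 0.197) and with free RNA genes left out by the profile of at most 50 UMIs (0.0591 to 0.15). By the second profile 6 of 8 tested kept theirs, and slc38a2 and ube2c did not (0.0676 to 0.0765). The class joins clusters 2 and 15, at 198 and 255, 271 and 316 cells in the anterior and 35 and 95, 31 and 97 in the posterior libraries, so its changes also compare different mixes. Lists called were G2/M -0.71 (2 of 20, 14 adjusted over the list alone, adjusted p = 1.08e-07), haem synthesis -1.16, embryonic globins -5.10 and erythroid and thrombocyte factors -1.12. At the estimated correlation no list passed, the lowest adjusted p being 0.664.

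Macrophage-like cells differed between regions in genes of several kinds, and the inflammatory list did not pass (median 0.164, mean -0.0509, adjusted p = 0.96). Posterior cells had more acod1 (-1.72 ± 0.23, adjusted p = 0.00415), which makes itaconate, the chemokine cxcl8a (-1.48 ± 0.20, adjusted p = 0.00415), fosb (-1.49 ± 0.22, adjusted p = 0.00694), jun (-0.94 ± 0.18, adjusted p = 0.0263), the iron exporter slc40a1 (-0.94 ± 0.17, adjusted p = 0.02), tsc22d3 (-1.18 ± 0.17, adjusted p = 0.00503) and the haem enzyme cpox (-0.97 ± 0.16, adjusted p = 0.0143). Anterior cells had more of the receptor s1pr2 (1.04 ± 0.20, adjusted p = 0.0315), nr4a3 (1.01 ± 0.17, adjusted p = 0.0153), the ceramide synthase cers2a (0.96 ± 0.16, adjusted p = 0.0132), cd83 (0.83 ± 0.15, adjusted p = 0.0244) and the proteasome gene psmb8a (1.28 ± 0.25, adjusted p = 0.0345). gata2b was at -0.24 ± 0.25 (adjusted p = 0.840). lyz (2.87 ± 0.15) had a bound of 107%, and hbae3 (-4.32 ± 0.54), slc4a1a (-4 ± 0.20), hbbe1.2 (-3.94 ± 0.66), hbbe2 (-3.78 ± 0.58) and hbbe1.3 (-3.58 ± 0.63) had 64.3, 35.1, 71.2, 65.1 and 64.3%. acod1, slc40a1 and tsc22d3 were chosen after their values were seen. Of 14679 genes 179 were called, 85 higher in anterior and 94 in posterior cells, and 119 had a bound over 10% while 60 had a low one by both profiles, 15 higher in anterior and 45 in posterior cells. With free RNA genes left out the calls were 4 against 24 and 4 against 28 by the profiles. Of 18 named genes 10 kept their call without any 1 library. s1pr2, nr4a3, jun, slc40a1, psmb8a and cpox lost it without anterior replicate 1 (adjusted p 0.0526 to 0.219), s1pr2, jun and psmb8a without posterior replicate 1 (0.0816 to 0.118), and s1pr2, nr4a3, cers2a, cd83, jun, psmb8a and cpox without anterior replicate 2 (0.0618 to 0.261). With free RNA genes left out, s1pr2, cd83, jun and psmb8a were lost by both profiles (0.0533 to 0.0778 and 0.0554 to 0.0789), and DESeq2 did not call hbbe1.2, hbbe1.3 and psmb8a (0.0729 to 0.141). Lists called were haem synthesis -0.827 (5 of 12, 9 adjusted over the list alone, adjusted p = 5.8e-08), lysosomal -0.324 (0 of 23, 6 adjusted over the list alone, adjusted p = 2.16e-04), MHC class I 0.315, embryonic globins -3.55, lymphoid 1.49, erythroid and thrombocyte factors -1.56 and stem factors -0.243. Under an estimated correlation the lowest adjusted p was 0.327. The class joins clusters 6 and 17, at 513 and 548, 515 and 548, 99 and 68, and 90 and 60 cells in the 4 libraries.

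The lymphoid-like cluster had few posterior cells, and its calls depend on the doublets. Anterior cells had more of the T cell factors satb1b (2.08 ± 0.29, adjusted p = 0.0116) and tcf7 (1.51 ± 0.22, adjusted p = 0.0123), her9 (1.79 ± 0.32, adjusted p = 0.0408), nr4a3 (1.53 ± 0.25, adjusted p = 0.0227), ccr9b (1.79 ± 0.34, adjusted p = 0.0495), egr1 (865 counts against 6, a fitted 2.31 ± 0.42, adjusted p = 0.0408) and the mitotic gene birc5a (2.12 ± 0.40, adjusted p = 0.0414, with bounds of 8.76 and 11.2% by the 2 free RNA profiles). More abundant in posterior cells were the chemokine receptor ccr6a (-1.33 ± 0.19, adjusted p = 0.0116), the receptor nitr9 (-1.03 ± 0.18, adjusted p = 0.0329) and the RFP transgene (-3.34 ± 0.28, adjusted p = 1.24e-04). RFP changed sign with the clustering, to 0.17 at resolution 2 and 3.33 with centred values, and was found in 2.39 and 2.59% of anterior cells and in 4.88% of 41 and 6.52% of 46 posterior cells. gata2b was at -1.62 ± 0.45 (adjusted p = 0.213). icn (5.94 ± 0.44) and lyz (2.90 ± 0.31) had bounds of 59.7 and 150%, and slc4a1a (-4.13 ± 0.54), hbae3 (-3.50 ± 0.19), hbbe1.1 (-3.49 ± 0.19), hbbe2 (-3.48 ± 0.21) and hbbe1.2 (-3.41 ± 0.22) had 69.6 to 102%. RFP, nr4a3, ccr6a and nitr9 were chosen after their values were seen. Of 12690 genes 70 were called, 32 higher in anterior cells (45.7%; 34.6% by DESeq2, whose median of all genes was -0.307), and 23 had a bound over 10% while 45 had a low one by both profiles (19 higher in anterior and 26 in posterior cells). With doublets kept 3 genes were called in all, and 15 of the 17 named genes lost their call (adjusted p 0.0579 to 0.0903). With centred values egr1, satb1b, tcf7, ccr9b and nitr9 lost it (0.1 to 0.811), and at resolution 2 egr1 and her9 did (0.0824 to 0.153). Of 17 named genes 7 kept their call without any 1 library. Without anterior replicate 2, 15 genes were called in all, and egr1, birc5a, satb1b, slc4a1a, tcf7, her9, nr4a3, ccr6a, ccr9b and nitr9 lost their call (adjusted p 0.055 to 0.42). So did egr1, slc4a1a, ccr9b and nitr9 without anterior replicate 1 (0.0713 to 0.175), birc5a and ccr9b without posterior replicate 1 (0.106 to 0.127), and egr1, her9, ccr9b and nitr9 without posterior replicate 2 (0.0665 to 0.151). Lists called were G2/M 0.922 (1 of 20, 9 adjusted over the list alone), embryonic globins -3.41, erythroid and thrombocyte factors -2.04, stem factors -1.13 and ribosomal -0.0793. With an estimated correlation the lowest adjusted p was 0.602.

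In cluster 10 anterior cells had more of the ETS factors etv5a (1.21 ± 0.22, adjusted p = 0.016) and etv5b (1.45 ± 0.27, adjusted p = 0.016), the blood group gene kel (0.92 ± 0.20, adjusted p = 0.0486) and the disulfide isomerase pdia2 (0.65 ± 0.13, adjusted p = 0.023). Higher in posterior cells were soul5 (-1.48 ± 0.16, adjusted p = 1.85e-04), ptgdsb.2 (-1.65 ± 0.34, adjusted p = 0.0325), eevs (-1.90 ± 0.38, adjusted p = 0.0268) and the homeobox gene pbx1a (-0.96 ± 0.18, adjusted p = 0.0157). gata2b was at 0.14 ± 0.131 (adjusted p = 0.820). cebpb (0.89 ± 0.15), gstp1 (0.70 ± 0.15) and lyz (2.66 ± 0.23) had bounds of 13.4, 24.3 and 102%, and hbae3 (-3.17 ± 0.22), hbbe1.3 (-2.71 ± 0.16), hbbe2 (-2.18 ± 0.19), hbbe1.1 (-2.01 ± 0.24) and hbbe1.2 (-1.98 ± 0.17) had 63.2 to 81.0%. The genes etv5a, etv5b, soul5, pbx1a, ptgdsb.2 and eevs were chosen after their values were seen. Of 13458 genes 172 were called, 147 higher in anterior and 25 in posterior cells, and 147 had a bound over 10% while 24 had a low one by both profiles, 8 higher in anterior and 16 in posterior cells. With free RNA genes left out, the 1 and 2 calls left by the profiles were all higher in posterior cells. Of 16 named genes 11 kept their call without any 1 library. gstp1, pdia2 and etv5b lost it without posterior replicate 1 (adjusted p 0.056 to 0.31), kel, gstp1 and pdia2 without anterior replicate 2 (0.0553 to 0.0941), and kel, pdia2 and etv5a without posterior replicate 2 (0.0547 to 0.112). With free RNA genes left out, 8 were still tested and kel, pdia2, etv5a, etv5b, pbx1a, ptgdsb.2 and eevs lost their call (0.164 to 0.276). By the second profile 9 were tested and these and cebpb lost it (0.121 to 0.246). DESeq2 did not call gstp1, etv5a, etv5b, ptgdsb.2 and eevs (0.0621 to 1), and with doublets kept kel, gstp1, ptgdsb.2 and eevs were lost (0.0529 to 0.0914). Without 1 library the calls ranged from 162 to 324. Lists called were S phase 0.259, immediate early 0.387, inflammatory 0.361, MHC class II 0.547, embryonic globins -2.0, myeloid 0.444, lymphoid 0.855 and ribosomal -0.197. At the estimated correlation no list passed, the lowest adjusted p being 0.358.

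Cluster 18 was marked by spink2-type and cst14b-type genes that themselves differ between regions, so those are not results. Anterior cells had more of the repressor gfi1ab (1.45 ± 0.28, adjusted p = 0.0168), the myeloid factor cebpb (1.07 ± 0.17, adjusted p = 0.00366), the homing receptor ccr9a (1.78 ± 0.29, adjusted p = 0.00379), xbp1 of the unfolded protein response (0.79 ± 0.15, adjusted p = 0.0168) and fosab (0.83 ± 0.18, adjusted p = 0.0352). More abundant in posterior cells were the erythropoietin receptor epor (-1.37 ± 0.31, adjusted p = 0.0416), and gata2b was at -0.02 ± 0.185 (adjusted p = 0.985). hbbe1.1 (-3.99 ± 0.25), hbbe1.3 (-3.43 ± 0.31), hbbe1.2 (-3.35 ± 0.37), hbae3 (-3.22 ± 0.24) and hbbe2 (-3.18 ± 0.27) had bounds of 67.1 to 103%. xbp1 was chosen after its value was seen. Of 9380 genes 144 were called, 120 higher in anterior and 24 in posterior cells, and 57 had a bound over 10% while 79 had a low one by both profiles (71 and 8). Of 11 named genes 7 kept their call without any 1 library. fosab, epor and xbp1 lost it without anterior replicate 1 (adjusted p 0.0919 to 0.0992) and without posterior replicate 2 (0.0678 to 0.202), and gfi1ab without posterior replicate 1 (0.0579). DESeq2 did not call gfi1ab, fosab and epor (0.0892 to 0.771), and with doublets kept hbbe1.3, hbbe1.2, hbbe2 and epor were lost (0.075 to 0.706). Without 1 library the calls ranged from 104 to 220. Lists called were immediate early 0.359, inflammatory 0.409, haem synthesis -0.602, embryonic globins -3.22, lysosomal 0.368, myeloid 0.587, erythroid and thrombocyte factors -1.40, stem factors -0.327 and ribosomal -0.0921. Under an estimated correlation the lowest adjusted p was 0.494.

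In cluster 3 anterior cells had more of the leukotriene enzyme lta4h (1.69 ± 0.30, adjusted p = 0.0145), the chromatin gene hmgn2 (1.17 ± 0.23, adjusted p = 0.0328), the nucleotide enzyme dut (1.32 ± 0.24, adjusted p = 0.0145) and slc1a5 (1.26 ± 0.27, adjusted p = 0.0464). Higher in posterior cells were the integrin itga4 (-1.13 ± 0.22, adjusted p = 0.0294) and cd74a, the MHC class II chaperone (near -1.13 ± 0.22, adjusted p = 0.0294). nqo1 (550 counts against 6, ratio 5.88, interval 2.69 to 16.1) and itga3a (1015 against 5, ratio 13.03, interval 5.56 to 40.2) rose, and for itga3a the bound was 0.372% by the first free RNA profile and 100% by the second. icn (1554 against 6, ratio 16.6, interval 7.62 to 45.4) and lyz (3.23 ± 0.31) had bounds of 55.5 and 150%, and hbbe1.1 (-5.48 ± 0.51), hbbe2 (-4.50 ± 0.24), hbae3 (-4.48 ± 0.33), hbae1.3 (-4.01 ± 0.39) and hbbe1.2 (-3.89 ± 0.23) had 53.6 to 92.8%. lta4h, hmgn2 and slc1a5 were chosen after their values were seen. Of 10746 genes 73 were called, 58.9% of them higher in anterior cells (43.6% by DESeq2, whose median of all genes was -0.235), and 51 had a bound over 10% while 11 had a low one by both profiles (7 higher in anterior and 4 in posterior cells). Of 15 named genes 10 kept their call without any 1 library. slc1a5, itga4 and cd74a lost it without anterior replicate 1 (adjusted p 0.0603 to 0.115), and nqo1, hmgn2, slc1a5 and itga4 without posterior replicate 2 (0.0506 to 0.177). Without 1 library the calls ranged from 56 to 225. Lists called were G2/M 1.14 (adjusted p = 2.02e-04), embryonic globins -4.01 and ribosomal -0.338. With an estimated correlation the lowest adjusted p was 0.625.

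Cluster 4 has no marker name. Anterior cells had more of the lymphoid genes il7r (3.57 ± 0.34, adjusted p = 1.05e-05) and rorc (2.01 ± 0.31, adjusted p = 0.00131), the Notch genes her9 (3.09 ± 0.32, adjusted p = 2.58e-05) and notch1b (1.35 ± 0.22, adjusted p = 0.00171), the corepressor tle3b (2.52 ± 0.31, adjusted p = 1.45e-04), hs6st1a (2.54 ± 0.29, adjusted p = 9.45e-05), myca (1.58 ± 0.24, adjusted p = 9.69e-04) and spi1a (1.2 ± 0.27, adjusted p = 0.0244). More abundant in posterior cells were the factors bcl11ba (-1.46 ± 0.18, adjusted p = 1.23e-04), tcf12 (-1.40 ± 0.19, adjusted p = 3.2e-04), sox13 (-2.92 ± 0.37, adjusted p = 2.17e-04) and klf2a (near -1.52 ± 0.20, adjusted p = 3.23e-04), the egress receptor s1pr4 (-1.73 ± 0.26, adjusted p = 9.69e-04), the adhesion genes cd44b (-1.39 ± 0.22, adjusted p = 0.00165) and itga4 (-1.19 ± 0.22, adjusted p = 0.0053), and the receptor kita (-2.06 ± 0.42, adjusted p = 0.0114). gata2b was at -0.54 ± 0.188 (adjusted p = 0.221). lyz (2.05 ± 0.26) had a bound of 127%, and slc4a1a (-4.78 ± 0.34), hbbe2 (-3.70 ± 0.20), hbae3 (-3.65 ± 0.19), hbbe1.1 (-3.54 ± 0.18) and rhag (-3.42 ± 0.23) had 64.6, 96.9, 102, 100 and 19.2%. rorc, myca, tcf12 and sox13 were chosen after their values were seen. Of 12093 genes 260 were called, 99 higher in anterior and 161 in posterior cells, and 114 had a bound over 10% while 139 had a low one by both profiles (36 and 103). Of 22 named genes 10 kept their call without any 1 library. Without anterior replicate 2, 33 genes were called in all, and lyz, bcl11ba, klf2a, s1pr4, cd44b, itga4, myca, notch1b, spi1a, tcf12 and kita lost their call (adjusted p 0.0632 to 0.442). Without anterior replicate 1, 66 were called, and rorc, s1pr4, cd44b, itga4, notch1b, spi1a, tcf12 and kita lost theirs (0.0584 to 0.254). So did s1pr4, itga4 and spi1a without posterior replicate 1 (0.0947 to 0.144) and spi1a and kita without posterior replicate 2 (0.0719 to 0.144). Lists called were Notch 0.62 (4 of 14, adjusted p = 0.0057; 0.385 with an estimated correlation), lymphoid 0.46 (3 of 13 higher and 2 lower, adjusted p = 0.0326), G2/M 0.336, haem synthesis -0.991, embryonic globins -3.30, erythroid and thrombocyte factors -1.55 and ribosomal -0.144. At the estimated correlation no list passed, the lowest adjusted p being 0.293.

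**Figure D3:**
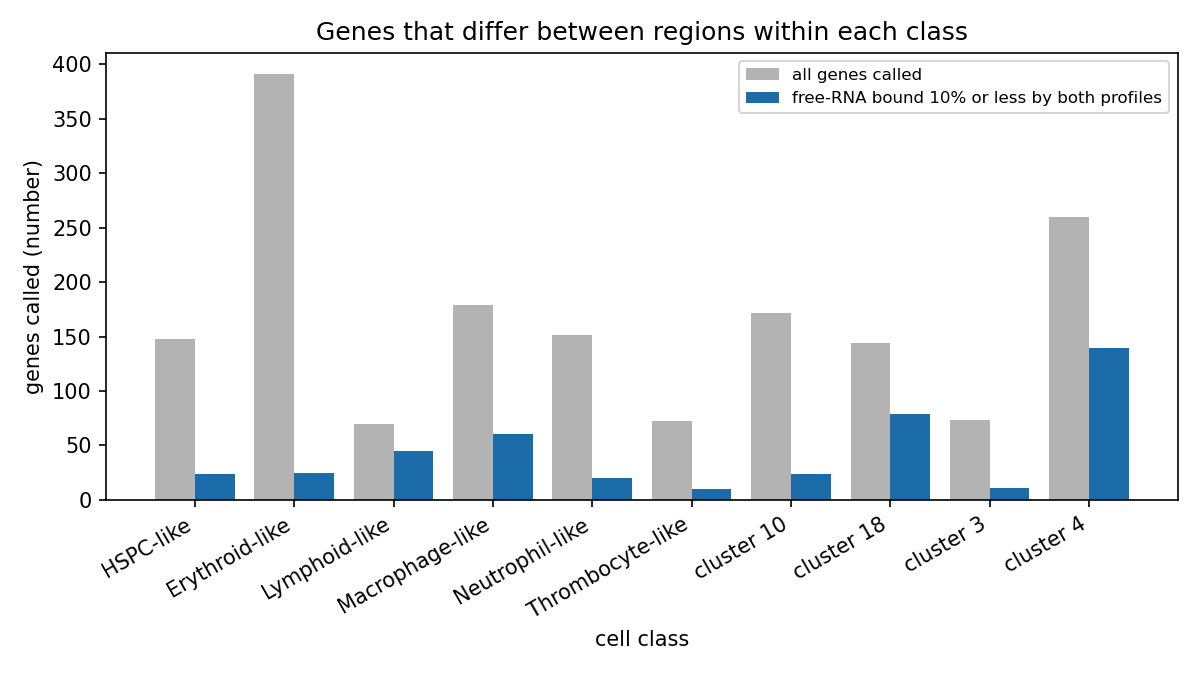
Genes called between regions in each class, all of them and those for which free RNA could supply 10% of the counts or less by both profiles.

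Whether the region effect in HSPC-like cells differs from that in another class was tested directly, with library as a factor. It differed for 236 of 14785 genes against cluster 4, among them myca (-1.75), s1pr4 (2.01) and tcf12 (1.54), named after their values were seen, for 219 of 14638 against erythroid-like cells and for 150 of 15150 against lymphoid-like cells. The other counts were 76 of 14742 against cluster 3, 74 of 15091 against macrophage-like cells, 70 of 14552 against cluster 10, 66 of 14876 against neutrophil-like cells, 42 of 12898 against cluster 18 and 26 of 12605 against thrombocyte-like cells, all by edgeR quasi-likelihood. Without a filter on low counts the counts were 2 for lymphoid-like cells, 30 for cluster 3, 152 for cluster 18, 130 for cluster 10 and 345 for erythroid-like cells. With the filter, the effect against erythroid-like cells was more anterior in HSPC-like cells for 16 genes and more posterior for 203. Genes with a high free RNA bound were kept, so these counts do not separate expression from free RNA that differs between classes.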

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

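The tests weighed below were all chosen after the results were seen. The items raised here are comparisons in which the region effect in HSPC-like cells differs from that in another class by a test of the difference itself, with edgeR and an adjusted p under 0.05. The number of such genes was 236 against cluster 4, 219 against Erythroid-like, 150 against lymphoid-like (T or NK), 76 against cluster 3, 74 against macrophage-like, 70 against cluster 10, 66 against neutrophil-like, 42 against cluster 18 and 26 against thrombocyte-like cells. Without a filter on low counts the counts were, in the same order, 203, 345, 2, 30, 90, 130, 73, 152 and 20. All of these tests kept genes with a high free RNA bound, so free RNA that differs between classes may be part of the counts.

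The first pattern weighed is the set of 122 genes called in HSPC-like cells with a free RNA bound over 10%. If free RNA caused these calls, at least 90% of them should share the direction of the free RNA profiles, and 99.2% did. The share was 79.2% of the 322 uncalled genes with a bound over 10%, so genes chosen by the bound agree often without a call, and the test cannot tell free RNA from expression in the same direction. This label was lowered from fits after the result was seen. For the 24 calls with a bound of 10% or less by both profiles the share was 87.5%, against 61% of all uncalled genes, and this cannot tell them apart either.

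The second pattern is the immediate early list in HSPC-like cells, with a median of 0.389, 2 of 19 members called higher in anterior cells and an adjusted p of 0.428 with an estimated correlation. Handling of the anterior libraries that acts on all cells alike should put the list median above 0 in at least 9 of 11 classes, and 10 were above 0. The sum of all blood cells is 1 of the 11 and not independent of the rest. HSPC-like cells, where the pattern was seen, are also among the 11, so their median was known to be above 0. The label here was lowered from fits to cannot tell after the result was seen, because macrophage-like cells had a median of -0.21 with 2 members called higher in posterior cells. Cluster 4 had 0 called higher in anterior and 1 in posterior cells, and neutrophil-like cells, cluster 10 and cluster 3 had 0 called.

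The third pattern is the lower share of HSPC-like cells in the anterior libraries. If erythroid-like cells filling the denominator caused it, they should hold the larger share in the anterior libraries, since a fuller denominator lowers every other share. Their log2 fold change was -3.735 ± 0.178, the opposite, which argues against that explanation. This value was already known when the prediction was written, so it is no independent test. A test used earlier, leaving these cells out, gave -2.43 and decides nothing, because its direction was fixed. Other classes do fill more of the anterior denominator: macrophage-like cells held 18.4 against 2.24%, T-lymphoid-like cells 13.3 against 0.0064% and neutrophil-like cells 8.98 against 1.83%. How far these lower the HSPC-like share was not tested, and neither was a difference between the tissues.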

How the results depend on the processing

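Across the alternatives, 358 recomputed values of shares and counts and 3208 of single genes kept their direction and side of the threshold or stayed close in size, while 84 values of shares and counts moved and 2 were weaker, and 309 of the single-gene values were weaker and 6 stronger. The cause was not tested unless stated. Where 1 library is left out, the lone sample is assumed to vary like the other group. In the test over the classes every share kept its direction and its call in all alternatives that gave one, which the HSPC-like share did not in the test over the clusters. With centred values no cluster was named dendritic-like, and the unnamed clusters have no counterpart in other clusterings. With 500 UMIs, anterior replicate 1 kept 15622 cells.

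Without 1 library, the share of HSPC-like cluster 7 ranged from -0.88 to -0.51, with adjusted p = 0.0546 at -0.61 (without posterior replicate 1) and 0.182 at -0.51 (without anterior replicate 2). Genes called ranged from 140 to 217 in HSPC-like cells, 182 to 448 in erythroid-like, 43 to 92 in thrombocyte-like, 107 to 260 in neutrophil-like, 96 to 399 in macrophage-like and 15 to 103 in lymphoid-like cells, and 162 to 324 in cluster 10, 104 to 220 in cluster 18, 56 to 225 in cluster 3 and 33 to 275 in cluster 4. HSPC-like subclusters past the threshold ranged from 0 to 1.

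Leaving out free RNA genes by construction tests fewer genes. It also takes out many genes with small p-values, which can raise the adjusted p of the genes that stay. In every class, a call lost this way by a gene still tested does not show that the gene depends on free RNA. By the profile of at most 50 UMIs and by that of over 50 and under 500, calls were 6 and 3 in HSPC-like, 1 and 20 in erythroid-like, 9 and 9 in thrombocyte-like, 5 and 25 in neutrophil-like and 28 and 32 in macrophage-like cells, 1 and 2 in cluster 10 and 147 and 158 in cluster 4. Cluster 18 had 88 by the first and cluster 3 had 43 by the second.

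Without a filter on low counts, calls were 475 in HSPC-like, 495 in macrophage-like, 330 in neutrophil-like, 118 in thrombocyte-like and 290 in lymphoid-like cells, 460 in cluster 10, 334 in cluster 18, 225 in cluster 3 and 414 in cluster 4. The test of the difference to HSPC-like cells gave 130 for cluster 10, 152 for cluster 18, 30 for cluster 3, 345 for erythroid-like and 2 for lymphoid-like cells. DESeq2 called 66 in cluster 18, 134 in cluster 4, 107 in lymphoid-like, 97 in neutrophil-like and 44 in thrombocyte-like cells. With doublets kept, calls were 118 in cluster 3, 3 in lymphoid-like, 277 in macrophage-like, 505 in neutrophil-like and 139 in thrombocyte-like cells.

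Replicates of the same number share only that number in the labels, and their deviations correlate at 0.243 in HSPC-like cells and 0.335 in all blood cells. With that number as a block, calls were 695 in HSPC-like, 1286 in erythroid-like, 521 in macrophage-like and 184 in lymphoid-like cells, 547 in cluster 10, 29 in cluster 3 and 484 in cluster 4, and lists called in cluster 3 were 6. Under the block nqo1, lta4h, hmgn2, dut, slc1a5 and itga4 in cluster 3 (adjusted p 0.0536 to 0.126) and junba and nusap1 in thrombocyte-like cells (0.0555 to 0.0763) were not called.

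With an estimated correlation, a setting with little power at 4 libraries, the lists called were 0 in all 11 sets. With fry they were 1 in HSPC-like cells, 0 in cluster 10, cluster 3 and neutrophil-like cells, 2 in cluster 18, and 3 in lymphoid-like, macrophage-like and thrombocyte-like cells.

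Reversals, 17 in all, were of single genes. Ranges are without 1 library. In HSPC-like cells pcna ranged from -0.0514 (without anterior replicate 2; -0.0226 without posterior replicate 1) to 0.109, ikzf1 from -0.0419 (without posterior replicate 1; -0.0385 without anterior replicate 2) to 0.159, top2a from -0.48 to 0.00506 (without anterior replicate 2) and mt-co2 from -0.28 to 0.0643 (without anterior replicate 1). At resolution 2 ikzf1 was at -0.0329 and notch1b at 0.00189. gata2b in erythroid-like cells ranged from -0.55 to 0.31 (without anterior replicate 2; 0.25 without posterior replicate 1) and was at 0.20 with doublets kept. It ranged from -1.23 to 2.17 (without posterior replicate 1) in neutrophil-like cells. In cluster 18 it ranged from -0.22 to 0.20 (without posterior replicate 2; 0.0594 without anterior replicate 2) and was at 0.0631 without a filter. RFP in lymphoid-like cells went to 0.17 at resolution 2 and 3.33 with centred values.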

Other observations

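The tests in this closing section were chosen after the results were seen. No GFP and no RFP UMI was counted in 76.5 to 83.5% of haematopoietic cells, which does not show that the transcripts were absent, since detection depends on depth and the cells were sorted by these reporters. In thrombocyte-like cells GFP was at 2417 and 1809 CPM in anterior and 2893 and 2147 CPM in posterior libraries, and itga2b at 195 and 142 against 239 and 220 CPM.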
